A study of Homo sapiens with 27 samples.

How the data were processed

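T cells of 10 patients with SLE and of 9 healthy controls were measured without stimulation, with arrays of 4 of the controls after NOC-18 (600 µM, 24 hr) and after CD3/CD28 (24 hr). Groups and replicate numbers come from the sample titles. RNA was extracted with RNeasy, labelled with biotin and amplified by a 2-cycle in vitro transcription protocol, per the labels. The deposited values are intensity, a linear signal per probe set, made by the authors with MAS5 in GCOS, per the submitters' processing notes, with no versions given. Detection calls were not used here. The deposited signal of each array had a trimmed mean of about 500 (500.04 to 500.07, with 2% trimmed from each end), so the values are relative to a common target, and a change of many genes in one direction is partly scaled away. Array medians ran from 107 to 303, and values from 0.267 to 349609. No value was at or below 0. The highest correlation between 2 arrays over all genes was 0.949, so no array was taken for a copy of another.

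Probe sets were named through the platform's annotation, matched by gene number to RefSeq genes of GRCh38.p14 for 41043 probe sets, with 0 symbols updated. Of 54675 probe sets, 62 were controls, 41097 had 1 symbol, 1801 several and 11777 none. The last 2 kinds entered no gene test. Of the probe sets of a gene, the one with the highest mean log2 value over all arrays was used, which left 19775 genes. Disagreement of the others is given for some genes only. Coordinates are not printed.

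Values were tested as log2(value + 16) with limma 3.58.1 (lmFit, eBayes with a mean-variance trend; R 4.3.3, the data.table package in version 1.17.8), so a change of a dim gene is understated. Genes were kept when their probe set lay above the array's median on at least as many arrays as the smallest group. SLE was compared with controls over 19 arrays. NOC-18, CD3/CD28 and the unstimulated arrays of the same 4 donors were fitted together over 12 arrays, without a donor term. P-values were two-sided and adjusted by Benjamini-Hochberg at 0.05. Lists of genes for 28 processes and 9 cell types were tested with camera (preset correlation 0.01, an estimated correlation beside it, and fry), with adjustment over process and cell type lists separately, and lists with at least 5 measured genes. List means per array were compared by exact permutation of 92378 splits. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

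The groups, the tests of genes and lists, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The permutation test of list means was added later, as were the alternatives named so in the closing section. The rule for named genes takes, per comparison, the 12 largest rises and 12 largest falls past the threshold, in the same direction in all 4 donors for the stimulated cells; where fewer than 10 genes pass, the 10 with the smallest p; the study genes; and up to 4 members of each list past the threshold, or the 1 or 2 with the smallest p. Genes of XIST, the Y chromosome and immune receptor segments are left out. Not every gene the rule takes is printed, and 1 of the 10 genes with the smallest p in SLE is not reported here.

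The design text says that the stimulated samples come from 4 of the control subjects, so the numbers pair them. Deviations of same-donor samples from their group means correlated from −0.0150 to 0.290 for NOC-18 and unstimulated, 0.0242 to 0.132 for CD3/CD28 and unstimulated, and 0.00516 to 0.0854 for both stimulated groups, and 3 of 4 samples correlated best with their own donor in each. The donor block was tried as an alternative, beside other pseudocounts (1 and 64), filters, normalizations, variance models, probe set rules, and leaving out each array. The tests were tried on simulated normal log2 values with the real means and spreads of 12527 genes for SLE and 14068 for the others, with 100 genes changed by 1 and 100 by 2 on the log2 scale. Of these, 39% and 89% were recovered for SLE, 33% and 77% for NOC-18, 27% and 73% for CD3/CD28, and 36% and 83% for their difference, with 5, 2, 5 and 7 false calls and 0 in the wrong direction. Array batches and scan dates are not given in the sources used here, so no batch was modelled.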

Results

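Gene expression was measured on 27 Affymetrix arrays of human T cells. There were 10 arrays of unstimulated T cells from patients with systemic lupus erythematosus (SLE), an autoimmune disease, and 9 of unstimulated T cells from healthy controls. For 4 of these controls there were also T cells kept for 24 hr with 600 µM NOC-18, a compound that releases nitric oxide slowly, and T cells stimulated for 24 hr through CD3 and CD28, the antigen receptor complex and its main costimulatory receptor. The other 5 controls had no stimulated arrays. Each array held 54675 probe sets, from which 1 probe set per gene was taken for 19775 named genes. The number of arrays limits the precision of every value. Samples of a group came from separate people, so the p-values measure the spread between people together with that between arrays.

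The arrays differed in ways their groups did not explain. Among the 19 unstimulated arrays, 6 had a median correlation with the others of at most 0.785, against at least 0.840 for the rest. These were control replicates 8 and 9 and SLE replicates 3, 5, 6 and 9. The median signal per array averaged 192 ± 43.5 (SD, n = 4) with NOC-18, 118 ± 9.52 (n = 4) with CD3/CD28, 177 ± 62.9 (n = 9) in unstimulated controls and 171 ± 31.5 (n = 10) in SLE. Spike-in transcripts, added during labelling or hybridization, averaged 13.30 ± 0.41, 12.33 ± 0.23, 12.89 ± 0.64 and 13.19 ± 0.56 on the log2 scale in the same order. The ratio of 3 prime to 5 prime signal of ACTB, which grows as RNA or its copies shorten, averaged 30.4 ± 8.05 with NOC-18, 16.6 ± 2.82 with CD3/CD28, 37.2 ± 19.7 in controls and 64 ± 39.2 in SLE. The same ratio of GAPDH had medians of 5.71, 3.23, 5.27 and 4.86 in that order, so it was not higher in SLE than in controls.

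**Figure D1:**
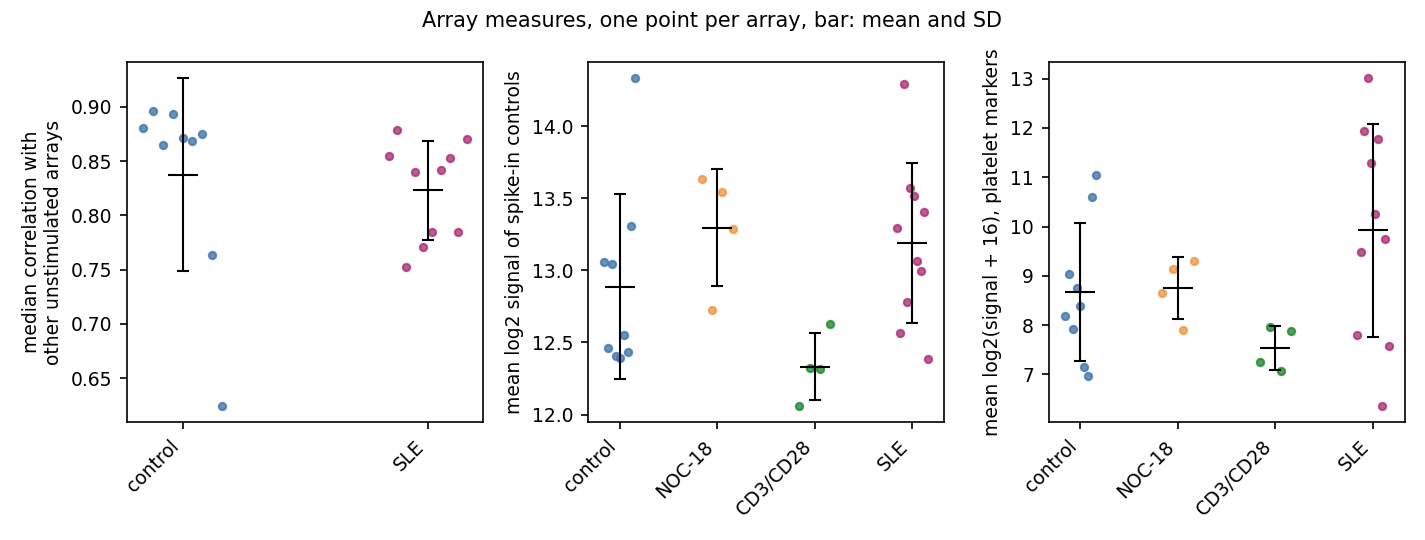
Each point is 1 array, grouped by condition, with bars for the mean and SD; the panels give the median correlation with the other unstimulated arrays (control and SLE only), the mean log2 spike-in signal and the mean log2 signal of the platelet markers. The CD3/CD28 arrays had the lowest mean spike-in signal, 12.33, and 6 unstimulated arrays had a median correlation of at most 0.785.

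The first comparison, of SLE with control T cells, asked which transcripts differ in the disease. No single gene differed beyond the spread between people. The immediate early genes, the transcription factors and regulators induced within minutes of a stimulus, were higher on average in SLE for all 23 measured members, with a median log2 difference of 0.93. Their mean was highest on control replicates 8 and 9 and SLE replicates 3, 4, 5, 6, 7 and 9, which also had the highest platelet marker means. The glucocorticoid-responsive genes had a median difference of 0.49 and the targets of p53, the transcription factor of the DNA damage response, one of 0.24. By camera with an estimated correlation between genes, none of the 28 process lists passed in SLE (smallest adjusted p = 0.108). Transcripts of the T cell receptor complex, of the mTOR pathway, of the endosome and of the lysosome had medians of −0.20, −0.03, 0.05 and −0.10, and with all 19 arrays and no covariates none of these 4 lists stood apart from the other genes.

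For single genes, limma called 0 of 12527 genes, with 1231 genes (9.83%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.348 (n = 10 and 9). The smallest unadjusted p values belonged to CAPZA2, a subunit of the actin capping protein (log2 difference 0.82 ± 0.17, SE; adjusted p = 0.348), and KIF12, a kinesin motor (−1.41 ± 0.29). Another 7 genes of the 10 with the smallest p were STON2, an endocytic adaptor (2.0), KMT2E (0.96), VTI1A, a vesicle fusion protein (0.92), RAB23 (−1.27), SURF6 (−0.82), GALT, an enzyme of galactose breakdown (−0.85), and MB21D2 (1.41). CAPZA2 was at 0.51 and VTI1A at 0.29 with the mean of probe sets, and without the 6 poorly correlating arrays MB21D2 was at 0.70.

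Of the 13 genes the study is about, none passed either over all genes or adjusted over the list alone. CD247, which encodes the ζ chain of the T cell receptor, was at −0.28 ± 0.28 (adjusted p = 0.756). Its mean was 12.42 ± 0.44 (SD, n = 10) in SLE and 12.70 ± 0.79 (n = 9) in controls. Its 2 probe sets pointed apart, since the one not used here gave 0.60 and their mean 0.16. Without control replicate 9 it was at −0.46 (adjusted p = 0.34). RAB4A, the gene of the Rab4 GTPase of endosome recycling, was at 0.09 ± 0.21, and MTOR, the kinase of the pathway, at −0.06. The MTOR value rested on control replicate 9, without which it was −0.36 (adjusted p = 0.378). TFRC, the transferrin receptor, which recycles through such endosomes, had the lowest p of the study genes, at 1.34 ± 0.43, with an adjusted p of 0.445 over all genes and of 0.0651 adjusted over the list alone. It was at 13.17 to 15.16 on control replicates 8 and 9 and SLE replicates 3, 4, 5, 6, 7 and 9. On the other unstimulated arrays it was at 11.33 to 12.48, except for SLE replicate 1 (13.39). LAMP1, a lysosomal membrane protein, was at 0.34 ± 0.16. Of the 5 TFRC probe sets 1 was at −0.20, and of the 4 LAMP1 probe sets 1 was at −0.14. The means of these probe sets were 0.58 and 0.16. FCER1G and SYK, the FcRγ chain and the kinase it recruits, were at 0.22 and 0.49. Of the unstimulated arrays both were highest on SLE replicates 1, 2 and 10 (FCER1G 11.21 to 12.41, SYK 9.95 to 10.37). Those 3 arrays also had the highest monocyte marker means (10.56 to 11.86). Monocytes express both genes, so these values are not shown to be those of T cells. ZAP70 was at 0.03, LCK, the Src family kinase of the receptor, at −0.66 ± 0.36, CD4 at −0.47, and CD3E, CD3G and CD3D at −0.27, −0.37 and −0.35. LCK without the 6 poorly correlating arrays was at −0.34, MTOR at −0.39, RAB4A at 0.29, FCER1G at 0.72 and SYK at 0.81, none past the threshold. Without SLE replicate 10, FCER1G turned to −0.05 and CD3E was at −0.03. FCER1G turned to −0.04 without SLE replicate 1 and ZAP70 to −0.18 without control replicate 3, while ZAP70 was at 0.17 without control replicate 5 and CD4 at −0.77 without control replicate 8.

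**Figure D2:**
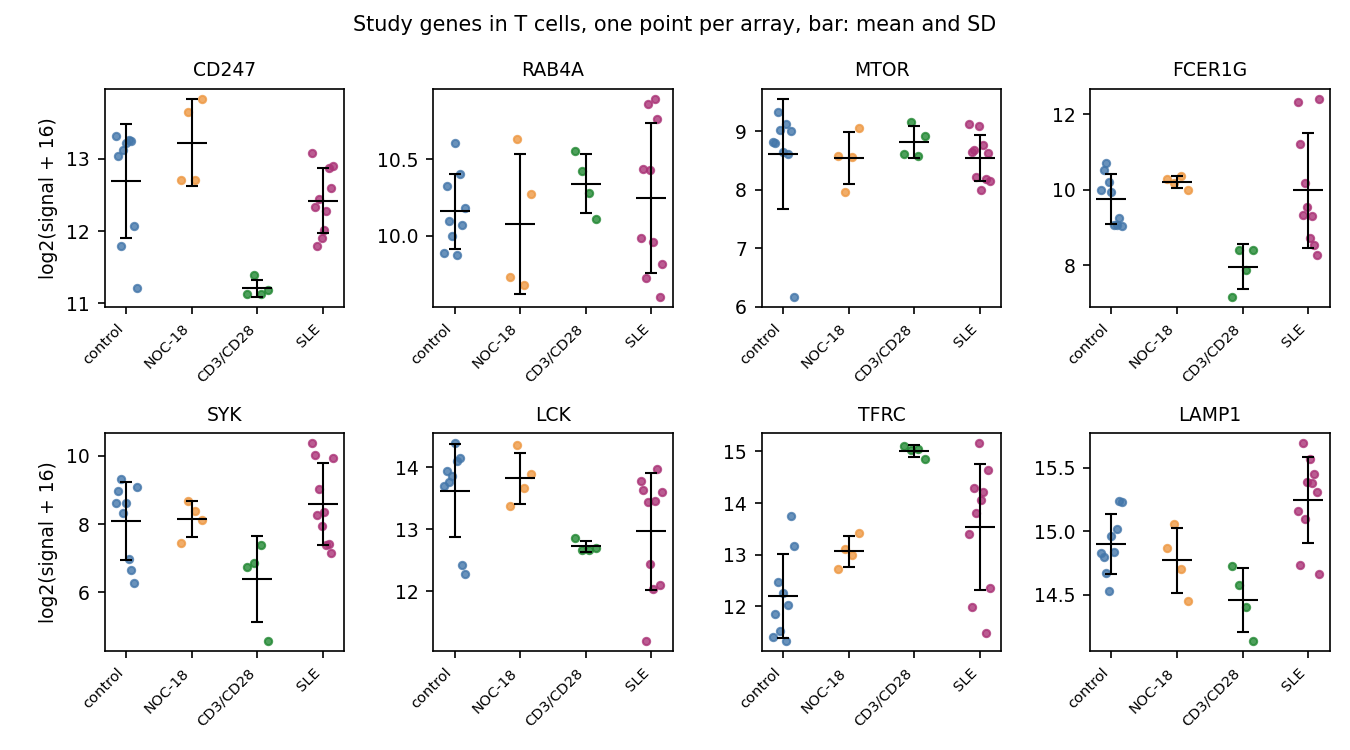
Mean log2 signal of study genes on each array, grouped by condition, with the mean and SD of each group. CD247 averaged 12.42 in SLE and 12.70 in unstimulated controls, and 11.21 after CD3/CD28.

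Of the 28 process lists, 7 were shifted upwards in SLE by camera, which tests a list against all other genes, with a preset correlation of 0.01 between genes. None of the 7 passed with an estimated correlation. The immediate early list had 0 of 23 members past the threshold over all genes or adjusted over the list alone (adjusted p = 6.36e-10, and adjusted p = 0.327 with an estimated correlation). NR4A2, a nuclear receptor of early activation, was at 3.01 ± 1.16 and KLF6 at 0.74 ± 0.29. The mean of the list was 12.99 to 13.96 on 8 arrays, the 6 poorly correlating ones with SLE replicates 4 and 7, and at most 11.61 on the other 11. The same 8 arrays had the highest platelet marker means, 9.75 to 13.01 against at most 9.47. With monocyte, granulocyte and platelet marker means as covariates the list's median was 0.33 and its call held. Glucocorticoid-responsive genes had 3 of 18 members higher adjusted over the list alone and 0 over all genes (adjusted p = 4.41e-06, and adjusted p = 0.108 with an estimated correlation). DDIT4, a stress-induced inhibitor of mTOR, was at 2.17 ± 0.61, MAP3K8 at 1.87 ± 0.49 and SGK1, a kinase induced by glucocorticoids, at 1.86 ± 0.62. Among 23 p53 targets, 20 were higher on average and 0 passed (adjusted p = 1.01e-04, and adjusted p = 0.108 with an estimated correlation), with GADD45A, a growth arrest gene, at 1.38 ± 0.54 and FAS, a death receptor, at 0.96 ± 0.38. FAS was at 0.03, KLF6 at 0.32 and SGK1 at 0.96 without the 6 poorly correlating arrays. Over the mean of probe sets the first 2 were at 0.46 and 0.47. GADD45A was at 12.31 to 13.57 on the 8 arrays with a high immediate early mean. On the other unstimulated arrays it was at most 10.55, except for SLE replicate 1 (12.13).

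T cell activation genes had 23 of 32 members higher on average, 0 past the threshold and 2 adjusted over the list alone (median 0.25, adjusted p = 4.67e-05; adjusted p = 0.244 with an estimated correlation). These 2 were CTLA4, an inhibitory receptor of activated and regulatory T cells (1.13 ± 0.30), and REL, an NF-κB subunit (1.22 ± 0.36). CTLA4 was at 0.24 with the mean of its probe sets. Without the 6 poorly correlating arrays the list's median was 0.13 and its adjusted p 0.0549, and without control replicate 7 its median was 0.11 and the call held. Hypoxia-induced genes had a median of 0.25, with 16 of 20 members higher, 0 past the threshold and 1, DDIT4, adjusted over the list alone (adjusted p = 5.15e-04; adjusted p = 0.244 with an estimated correlation; median 0.09 without SLE replicate 1, still called). Cell cycle genes had a median of 0.21 and 0 of 33 past the threshold, with 1, RRM2, a subunit of ribonucleotide reductase (1.63 ± 0.43), adjusted over the list alone (adjusted p = 0.0178; adjusted p = 0.35 with an estimated correlation). That call ended without control replicate 7 (median 0.12, adjusted p = 0.0639), without SLE replicate 2 (0.15, adjusted p = 0.13), and with markers of other blood cells as covariates (−0.02, adjusted p = 0.964). It held without control replicate 5, SLE replicate 1 or SLE replicate 5, at medians of 0.13, 0.13 and 0.12.

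Type I interferon response genes, often raised in SLE blood, had a median of 0.30, with 27 of 39 higher and 0 past the threshold or adjusted over the list alone (adjusted p = 0.0178; adjusted p = 0.842 with an estimated correlation). CMPK2 was at 1.71 ± 0.92 and IFI35 at −0.97 ± 0.41. Without the 6 poorly correlating arrays the list turned to −0.62 (adjusted p = 1.56e-05) and CMPK2 to −0.32. Leaving out any 1 of 8 arrays (control replicates 6, 7, 8 or 9; SLE replicates 3, 6, 9 or 10) gave medians of 0.18, 0.29, 0.15, 0.14, 0.10, 0.22, 0.09 and 0.28 and adjusted p values of 0.199, 0.0589, 0.355, 0.314, 0.186, 0.0664, 0.261 and 0.0751. The call held without control replicates 1, 3 or 5, at medians of 0.49, 0.46 and 0.20.

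Of the markers of other blood cells, 2 lists were called with the preset correlation only. All 9 platelet markers were higher on average in SLE (median 1.24, adjusted p = 1.86e-04; adjusted p = 0.518 with an estimated correlation), as were all 12 neutrophil and granulocyte precursor markers (median 0.63, adjusted p = 0.00151; adjusted p = 0.518 with an estimated correlation). In both lists 0 members passed over all genes or adjusted over the list alone. SPARC and TUBB1 of the platelet list were at 1.99 ± 0.93 and 2.08 ± 1.18, and MMP9 and LTF of the neutrophil list at 1.37 ± 0.55 and 1.23 ± 0.81. TUBB1 was at 1.33 with the mean of its probe sets, and LTF at 0.81 without control replicate 9. The neutrophil call ended without SLE replicate 2 (median 0.35, adjusted p = 0.0644). Both calls ended with the marker means as covariates (adjusted p = 0.99 each), which by construction takes their own signal out. Monocyte, B cell, plasma cell, NK cell and erythrocyte markers had medians of 0.06, 0.16, 0.26, 0.00 and 0.30, and T cell markers one of −0.27, with no call. Without the 6 poorly correlating arrays the monocyte list was called, with a median of 0.67 (adjusted p = 0.00598).

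The lists with no call in SLE included the mTOR pathway (31 genes, adjusted p = 0.342), the early and recycling endosome (33, adjusted p = 0.342), the lysosome (32, adjusted p = 0.463) and the T cell receptor complex with its proximal signalling (25, adjusted p = 0.812), each with 0 members past the threshold or adjusted over the list alone. The mTOR list's median of −0.03 and mean of 0.09 differ in sign. CD2 (0.83 ± 0.30) and VAV1 (0.75) had the smallest p of the receptor list, but both were at 0.01 without the 6 poorly correlating arrays. Oxidative phosphorylation genes had a median of −0.19, with 4 of 37 higher (adjusted p = 0.116), and were past the threshold after quantile normalization (adjusted p = 0.00139) and with no filter (0.0361). They also passed without control replicate 8 (median −0.28, adjusted p = 0.0238), control replicate 9 (−0.33, 3.53e-04), SLE replicate 2 (−0.25, 0.0329) or the 6 poorly correlating arrays (−0.26, 8.07e-04). Their median was −0.08 without control replicate 3. The lysosome list was called without those 6 arrays, with its median turned to 0.14 (adjusted p = 0.0436), and with marker covariates, at 0.31 (adjusted p = 1.42e-05).

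Averaged per array, 2 of 37 lists had an unadjusted p under 0.01 in an exact two-sided permutation test over all 92378 splits, and none passed after adjustment. The mean of the p53 targets was 10.07 ± 0.32 (SD, n = 10) in SLE and 9.69 ± 0.13 (n = 9) in controls (exact permutation p = 0.00378, adjusted p = 0.0821). All 10 SLE arrays lay above the control median and 6 above every control. The mean of the glucocorticoid-responsive genes was 11.81 ± 0.51 against 11.12 ± 0.34 (exact permutation p = 0.00444, adjusted p = 0.0821). Here 9 SLE arrays lay above the control median and 7 above every control. Dendritic cell markers, too few for camera, differed by −0.66 (exact permutation p = 0.0312, adjusted p = 0.211). The mean of the immediate early genes differed by 1.15 (exact permutation p = 0.0802, adjusted p = 0.371).

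**Figure D3:**
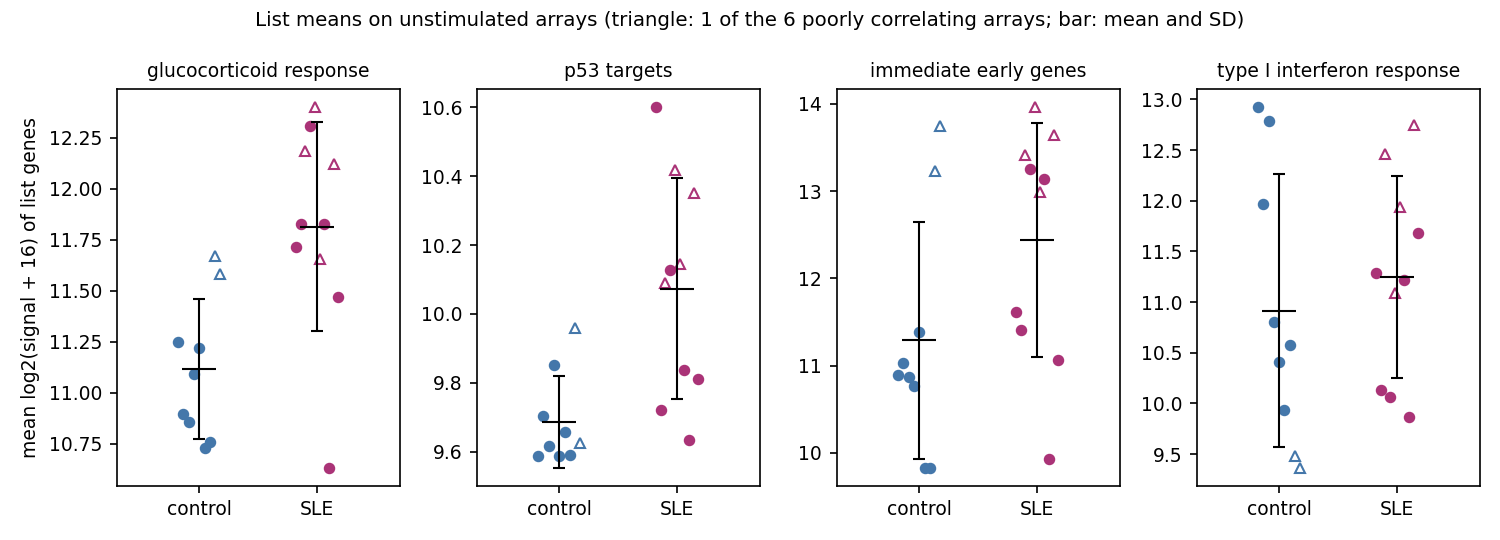
Mean log2 signal of the members of selected gene lists on each unstimulated array, control (n = 9) and SLE (n = 10), with group means and SD; triangles mark the 6 poorly correlating arrays. The glucocorticoid-responsive mean lay above every control on 7 of 10 SLE arrays and the p53 target mean on 6.

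The second comparison asked what nitric oxide changes in control T cells. After NOC-18, genes induced by low oxygen, genes of glycolysis and p53 targets rose together, while MYC, which drives growth and proliferation, and CCL2, a chemokine that attracts monocytes, fell. VEGFA, the angiogenic growth factor, rose from 7.84 ± 0.27 (SD, n = 4) to 10.93 ± 0.36, a log2 change of 3.10 ± 0.28 (SE; adjusted p = 1.94e-05). DDIT4, the stress-induced inhibitor of mTOR, rose by 2.88 ± 0.21 (adjusted p = 1.03e-06). Neither rise was particular to NOC-18. With CD3/CD28 the means were 10.49 for VEGFA and 13.86 for DDIT4, against 10.93 and 13.10 with NOC-18. The p53 target GADD45A was at 12.24 and 12.33. P4HA1 (10.02 and 11.69), AEN (11.06 and 11.97) and HMOX1 (7.46 and 9.48) were higher with NOC-18. Over all 9 unstimulated controls DDIT4 ran from 9.90 to 13.53. Of the 13 study genes only TFRC changed, with a rise of 1.24 ± 0.21 (adjusted p = 0.00345), also the only 1 adjusted over the list alone. That call ended with the mean of its probe sets, at 0.97 (adjusted p = 0.0983). The other TFRC probe sets were at 0.67 to 1.24, of which that at 1.01 passed in limma over all probe sets (adjusted p = 0.0133).

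In all, limma called 403 of 14068 genes, of which 127 rose and 276 fell (31.5% higher), and 224 changed by at least 2-fold. The largest rises that ran the same way in all 4 donors, besides those of VEGFA and DDIT4, included MIR210HG, the host transcript of a microRNA induced by low oxygen (3.08), OSM, the cytokine oncostatin M (3.01), NR4A3 (2.57) and the ribosomal RNA gene RNA45SN5 (2.64). Further rises were of SCARNA2 (2.52), P4HA1, a collagen prolyl hydroxylase (2.35), and AEN, a nuclease induced by p53 (2.26). The largest falls included CCL2 (−3.85 ± 0.80, adjusted p = 0.0143), GATB (−2.56), LRBA (−2.46 ± 0.26, adjusted p = 4.88e-05), and DPYD (−2.44), which breaks down pyrimidines and has another probe set in the opposite direction. With the mean of probe sets GATB was at −0.74 (adjusted p = 0.231) and DPYD at −0.33 (adjusted p = 0.748). Others were SNX29 (−2.18), MYC (−2.18 ± 0.27, adjusted p = 1.75e-04) and CPT2 of fatty acid oxidation (−2.13).

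Of 20 measured hypoxia-induced genes 14 rose and 0 fell, and 16 rose and 1 fell adjusted over the list alone (median 1.01, camera adjusted p = 2.3e-22; adjusted p = 0.00337 with an estimated correlation). ANKRD37 (2.08 ± 0.24) was among them, and BNIP3 and BNIP3L, which direct mitochondria to autophagy, rose by 1.77 ± 0.19 and 1.08 ± 0.21. Of 22 glycolysis genes 14 rose and 0 fell, or 17 and 1 adjusted over the list alone (median 0.90, adjusted p = 2.44e-17; adjusted p = 0.0115 with an estimated correlation). Among them were ALDOC (1.83 ± 0.30) and GAPDH (1.79 ± 0.32; control replicate 3 stood apart at 12.72), both enzymes of the pathway. Others were ENO2, an enolase (1.61 ± 0.17), and SLC2A3, a glucose transporter (1.54 ± 0.24). Of 23 p53 targets 11 rose and 0 fell, or 18 and 0 adjusted over the list alone (median 1.15, adjusted p = 3.28e-21; adjusted p = 0.00155 with an estimated correlation). Examples were GADD45A (2.08 ± 0.21), the death receptor gene TNFRSF10B (1.91 ± 0.20), the DNA repair gene DDB2 (1.90 ± 0.19) and the sestrin gene SESN1 (1.43 ± 0.24).

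**Figure D4:**
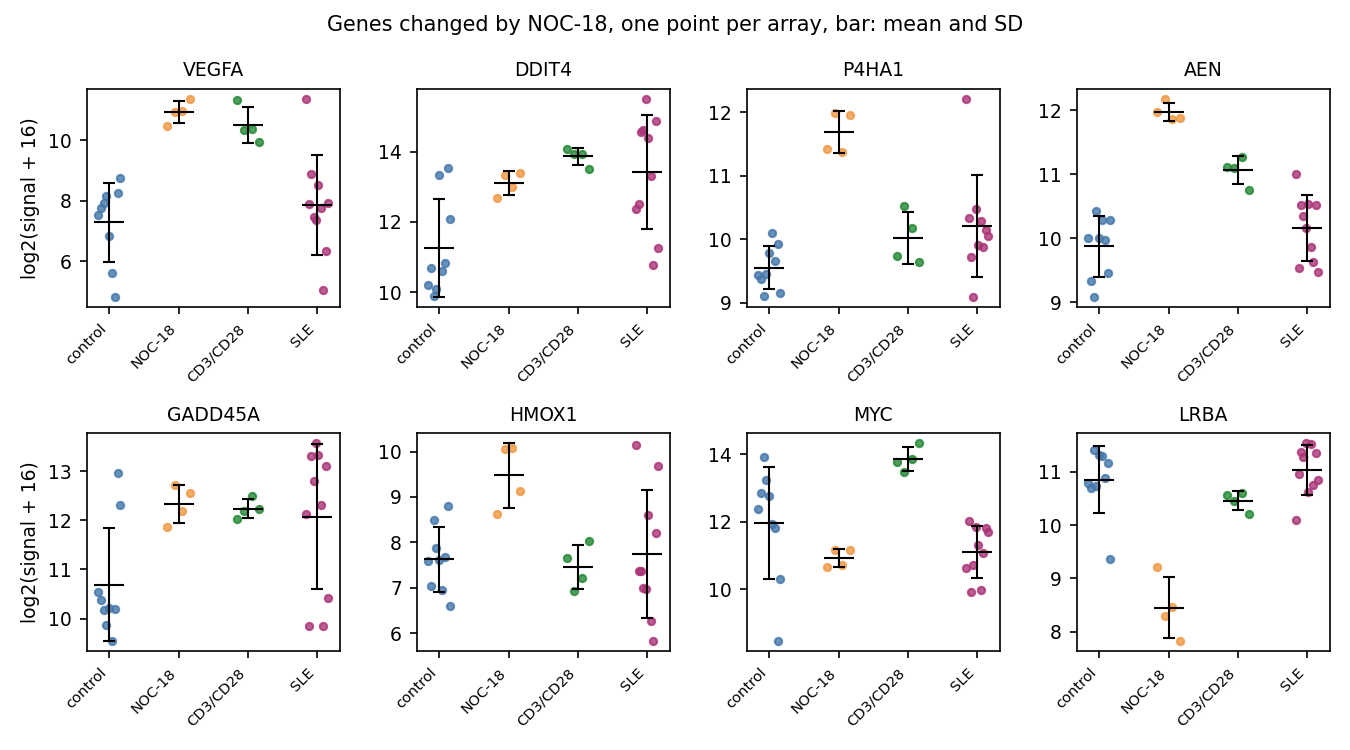
Log2 signal of 8 genes named for NOC-18 on each of the 27 arrays, grouped by condition, with bars for the mean and SD; the control group holds all 9 unstimulated controls, of which only 4 entered the test. VEGFA averaged 7.29 in the 9 controls, 10.93 with NOC-18, 10.49 with CD3/CD28 and 7.85 in SLE.

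A further 7 process lists were called with the preset correlation only. Immediate early genes had 4 of 22 rising and 0 falling, or 8 and 1 adjusted over the list alone (median 0.33, adjusted p = 2.55e-04; adjusted p = 0.0726 with an estimated correlation). They included NR4A2 (1.76 ± 0.30) and ATF3, a stress-induced repressor (1.82 ± 0.29), which was at 0.47 with the mean of its probe sets (adjusted p = 0.507). Antioxidant genes and NRF2 targets had 4 of 26 rising and 0 falling, or 5 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.0385; adjusted p = 0.44 with an estimated correlation). HMOX1, the inducible heme oxygenase, rose by 1.72 ± 0.40 (adjusted p = 0.0266), and TXNRD1, thioredoxin reductase, by 0.81 ± 0.19, although over the mean of its probe sets it was at 0.01 with an adjusted p of 0.995. The HMOX1 call ended without control replicate 1 (adjusted p = 0.0689) or 2 (0.0857), or NOC-18 replicate 2 (0.0642) or 3 (0.102). The TXNRD1 call ended without control replicate 1 (adjusted p = 0.0591), 2 (0.0508) or 4 (0.0827), or NOC-18 replicate 2 (0.0533) or 3 (0.091). That list's call ended with 75th percentile scaling (adjusted p = 0.0592), with no filter (0.0596), and without control replicate 1 (0.13), control replicate 4 (0.175) or NOC-18 replicate 2 (0.344, median 0.12).

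Type I interferon response genes had 0 of 40 past the threshold or adjusted over the list alone and 38 below 0 (median −0.65, adjusted p = 8.84e-06; adjusted p = 0.695 with an estimated correlation). That median was −0.38 without control replicate 1 or 3 and −1.04 without control replicate 4, each still called. Unstimulated controls 1, 2 and 3 had list means of 12.92, 11.97 and 12.78, against 9.37 to 10.80 in the other controls. The mean of donor 4 moved only from 10.80 to 10.72, so the fall lay in donors who began high. IFITM1 was at −0.87 (adjusted p = 0.0853) and EPSTI1 at −1.37 ± 0.44 (adjusted p = 0.109). With the donor as a block, which takes each person's own level out, both passed (adjusted p = 0.027 and 0.019). IFITM1 also passed after quantile normalization (adjusted p = 0.0396). Without control replicate 4, IFITM1 (adjusted p = 0.0265), EPSTI1 (0.0466) and the metallothionein MT1E (0.0298) passed. Metallothioneins, which bind zinc and copper, had 0 of 8 past the threshold and 4 lower adjusted over the list alone (median −0.74, adjusted p = 3.89e-04; adjusted p = 0.323 with an estimated correlation), with MT1E at −1.20 ± 0.36. Their median was −0.42 without control replicate 3, still called. Heat shock genes had 0 of 16 past the threshold and 1 lower, HSPE1 (−0.83 ± 0.22), adjusted over the list alone (median −0.34, adjusted p = 0.00565; adjusted p = 0.323 with an estimated correlation). HSPE1 passed after quantile normalization (adjusted p = 0.0312) and without NOC-18 replicate 2 (0.0147). Cytosolic ribosomal protein genes had 0 of 30 past the threshold or adjusted over the list alone, all 30 above 0 (median 0.38, adjusted p = 4.95e-10; adjusted p = 0.251 with an estimated correlation). After quantile normalization that median was 0.01 and the call ended (adjusted p = 0.591). Ribosome biogenesis genes had 0 of 26 past the threshold and 5 lower adjusted over the list alone (median −0.21, adjusted p = 0.0194; adjusted p = 0.236 with an estimated correlation), a call lost after quantile normalization (0.0622) and without control replicate 2 (0.0641).

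Several lists held single genes that changed without a call for the list. In the mTOR list, 2 of 34 members rose, DDIT4 and SESN1, both inhibitors of the pathway, and 0 fell, or 3 and 0 adjusted over the list alone (median 0.01, adjusted p = 0.0879). In the list of ATF4 targets and the unfolded protein response, ATF3 rose, while PSAT1 of serine synthesis (−2.04 ± 0.19) and ASNS, asparagine synthetase (−0.87 ± 0.19), fell (1 and 2 of 26, or 4 and 2 adjusted over the list alone; adjusted p = 0.697). T cell activation genes had 2 falls of 33, MYC and SOCS3, a feedback inhibitor of cytokine signalling (−1.95 ± 0.25), also 2 adjusted over the list alone (adjusted p = 0.101). With the mean of probe sets ASNS was at −0.40 (adjusted p = 0.404) and SOCS3 at −0.52 (adjusted p = 0.419), and ATF3 lost its call as well. The ASNS call also ended without NOC-18 replicate 3 (adjusted p = 0.0631) or 4 (0.0507). PCNA, the replication clamp and also a p53-responsive gene, was the only 1 of 39 cell cycle genes to change, with a rise of 1.83 ± 0.18 (1 adjusted over the list alone). In the lysosome list 2 of 33 genes fell, the cathepsins CTSC (−0.97 ± 0.24) and CTSL (−0.83 ± 0.22), also 2 adjusted over the list alone (adjusted p = 0.28). With the mean of probe sets neither passed (adjusted p = 0.186 and 0.0713). The CTSC call ended without control replicate 1, 2 or 3 (adjusted p = 0.0627, 0.0965 and 0.104) or NOC-18 replicate 1, 3 or 4 (0.0917, 0.11 and 0.118). The CTSL call ended without control replicate 1, 2, 3 or 4 (adjusted p = 0.0501, 0.0654, 0.118 and 0.0831) or NOC-18 replicate 1, 3 or 4 (0.14, 0.072 and 0.107). In the mitochondrial list 2 of 23 rose, BNIP3 and BNIP3L, and 3 fell, or 4 and 6 adjusted over the list alone, with UCP2, an inner membrane carrier, at −1.75 ± 0.32 (adjusted p = 0.28). The endosome list had 2 rises of 33, or 2 rises and 1 fall adjusted over the list alone (adjusted p = 0.851), and the T cell receptor list 0 of 25 (adjusted p = 0.797). Without NOC-18 replicate 2 the lysosome (adjusted p = 0.0115) and T cell activation (0.0143) lists passed, and the latter also without control replicate 4 (0.0046) and with no filter (0.0174). The mTOR list passed without NOC-18 replicate 1 (0.0405) or 3 (0.0343).

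CD247 was at 0.41 ± 0.30 after NOC-18 (adjusted p = 0.544), RAB4A at 0.00, MTOR at −0.44 and CD3G at −0.46. For LAMP1 the probe sets pointed apart, with 1 at 0.06 and another at 1.47 (unadjusted p = 0.00701). None of the cell type lists was called. Monocyte markers had a median of −0.44 (adjusted p = 0.328), erythrocyte markers 0.75 (adjusted p = 0.328) and NK cell markers 0.57 (adjusted p = 0.475).

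The count of 403 depended on the setting and on single arrays. It was 519 with the donor as a block, 267 with 75th percentile scaling, 237 without the trend in the variance, 203 with the mean of the probe sets of each gene, 169 with only the 2 groups in the fit, 119 with all 9 controls as baseline and 128 with the spike-in signal as a covariate (53.1% then higher). Leaving out NOC-18 replicate 3, control replicate 2 or NOC-18 replicate 1 gave 215, 242 and 257. The labels do not say whether the unstimulated cells were cultured, so against these cells the culture time cannot be told apart from either stimulus. The NOC-18 and CD3/CD28 arrays had the same culture time, which cannot by itself set them apart. Between them 5846 of 14068 genes differed. T cell activation genes were lower with NOC-18 (median −2.14) and p53 targets higher (1.42). Both passed in camera with an estimated correlation (adjusted p = 0.00731 and 0.0426). For these genes and lists this argues against culture as the whole cause of both changes at once. It does not tell which of them departs from culture, so for either change alone culture stays open. Elsewhere, as for glycolysis genes, it stays open for both.

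The third comparison gave the response to stimulation of CD3 and CD28. Genes of cytokines, activation and cell division rose, and genes of the resting T cell fell. IL2, the T cell growth factor, rose by 8.88 ± 0.43 on the log2 scale (n = 4 and 4; adjusted p = 1.79e-10), IFNG, interferon γ, by 5.68 ± 0.55 and TNF by 5.59 ± 0.23. PIK3IP1, an inhibitor of PI3 kinase in resting T cells, fell by 5.09 ± 0.14 on the log2 scale (adjusted p = 1.25e-13), and KLF2, a quiescence factor, by 4.04 ± 0.27. CD247, the ζ chain gene, fell by 1.61 ± 0.30 (adjusted p = 3.89e-04).

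Limma called 5109 of 14068 genes, of which 2260 rose and 2849 fell (44.2% higher), with 3397 changed by at least 2-fold. The median of all genes was −0.20, and it moved by 0.19 with quantile normalization and by 0.29 with 75th percentile scaling, so changes of that size depend on the scaling. With 75th percentile scaling 4797 genes were called and 63.6% of them were higher. The largest rises were of ZBED2 (9.18 ± 0.42), IL2, LTA, lymphotoxin α (6.34 ± 0.49), LIF (6.16 ± 0.46), IFNG, TNF, EPOP (5.47), IL3 (5.36) and IL17F (5.36). Others were CDC20, an activator of mitotic exit (5.20 ± 0.58), ZBTB32 (4.81) and TNFRSF9, the costimulatory receptor 4-1BB (4.80 ± 0.37). The largest falls were of DPEP2 (−6.00 ± 0.29), LYZ, the lysozyme gene of monocytes (−5.69 ± 0.98), MEGF6 (−5.13), PIK3IP1, CSGALNACT1 (−5.03) and APBA2 (−4.65). Others were ADA2 (−4.63), P2RY10 (−4.62), S100A8 (−4.45 ± 0.98), GIMAP4, a GTPase of lymphocyte survival (−4.43 ± 0.25), ATM, the DNA damage kinase (−4.36 ± 0.25), and GPA33 (−4.32).

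Among the lists, 6 held with both the preset and an estimated correlation. T cell activation genes rose in 26 of 33 cases, also 26 adjusted over the list alone, and 0 fell (median 2.03, adjusted p = 6.73e-17; adjusted p = 0.00572 with an estimated correlation). TNFRSF4 was at 4.61 ± 0.52, CTLA4 at 4.35 ± 0.17, IRF4 at 4.16 ± 0.25 and IL2RA, the high-affinity chain of the IL-2 receptor, at 3.81 ± 0.31. Of 25 cytokines and chemokines 18 rose and 3 fell, the same counts as adjusted over the list alone (median 2.79, adjusted p = 2.99e-10; adjusted p = 0.00823 with an estimated correlation). Of 39 cell cycle genes 30 rose and 0 fell, also 30 adjusted over the list alone (median 1.60, adjusted p = 4.76e-14; adjusted p = 0.00823 with an estimated correlation). UHRF1 was at 4.70 ± 0.54, GINS2 at 4.41 ± 0.40 and MCM2, part of the replicative helicase, at 4.16 ± 0.22. Of 26 ribosome biogenesis genes 21 rose and 1 fell, the same adjusted over the list alone (median 1.60, adjusted p = 9.78e-15; adjusted p = 0.00193 with an estimated correlation), RRP9 by 3.54 ± 0.41.

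ATF4 targets and unfolded protein response genes rose in 17 of 26 cases and fell in 2, or 18 and 2 adjusted over the list alone (median 1.19, adjusted p = 4.13e-09; adjusted p = 0.00572 with an estimated correlation). These rises included PSAT1 (3.27 ± 0.19), the amino acid transporter gene SLC7A5 (3.22 ± 0.21) and ASNS (2.81 ± 0.19). Of 23 quiescence and naive state genes 19 fell and 1 rose, the same adjusted over the list alone (median −1.44, adjusted p = 2.36e-10; adjusted p = 0.00823 with an estimated correlation), with KLF3 at −3.03 ± 0.21.

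The T cell receptor complex and its proximal signalling had 13 of 25 genes falling and 1 rising, the same adjusted over the list alone (median −0.69, adjusted p = 0.00959; adjusted p = 0.199 with an estimated correlation). With CD247, LCK fell by 1.09 ± 0.18 (adjusted p = 1.15e-04), CD3G by 0.59 ± 0.18 (adjusted p = 0.0157) and UBASH3A, a phosphatase family inhibitor of receptor signalling, by 1.49 ± 0.22. FCER1G fell by 2.40 ± 0.28 (adjusted p = 2.58e-06) and SYK by 2.42 ± 0.52 (adjusted p = 0.00117). Neither is typical of resting T cells, and both are expressed by monocytes, whose markers fell on the same arrays. Of the 13 study genes 6 changed, also 6 adjusted over the list alone. CD3E (−0.69, adjusted p = 0.0769), CD3D (−0.32, adjusted p = 0.15), CD4 (−0.44) and ZAP70 (0.06) did not pass. The other CD247 probe set was at −0.24, with the mean of both at −0.92 (adjusted p = 0.0717), and 1 of the 4 SYK probe sets was at 0.17. TFRC rose by 3.19 ± 0.21 (adjusted p = 4.63e-09), with another of its 5 probe sets at 3.26 and 2 below 0. RAB4A was at 0.27 (adjusted p = 0.402), MTOR at −0.17 (adjusted p = 0.676) and LAMP1 at −0.25 (adjusted p = 0.279). After quantile normalization CD3D (−0.69, adjusted p = 7.78e-04) and LAMP1 (−0.54, adjusted p = 0.0141) passed, and MTOR turned to 0.10. The LAMP1 probe sets pointed apart, with another at 1.27 (unadjusted limma p = 0.0174) and their mean turned to 0.33 (adjusted p = 0.272). The CD3G call ended without control replicate 2 (adjusted p = 0.0534) or CD3/CD28 replicate 3 (0.0699), and CD3E passed without control replicate 3 (0.0258).

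In the mTOR list 7 of 34 genes rose and 9 fell, the same adjusted over the list alone, with no call for the list (median −0.14, adjusted p = 0.902). Its members moved apart, with the inhibitors DDIT4 and SESN2 rising by 3.64 ± 0.21 and 2.58 ± 0.43, and SESN3, another sestrin, at −3.43 ± 0.25 and PIK3R1, the regulatory subunit of PI3 kinase, at −2.64 ± 0.23. In the endosome list 7 of 33 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.0894), RAB11FIP1, an effector of Rab11 recycling, by 3.06 ± 0.22. In the lysosome list 2 of 33 rose and 10 fell, or 2 and 11 adjusted over the list alone (median −0.27, adjusted p = 0.18), with SCARB2 at −1.91 ± 0.24 and the cathepsin gene CTSS at −1.88 ± 0.20. The lysosome list passed with quantile normalization (adjusted p = 0.0363), and the endosome list with 75th percentile scaling (adjusted p = 0.0391), with no filter (adjusted p = 0.0404) and without control replicate 2 (adjusted p = 0.0488).

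Lists called with the preset correlation only included oxidative phosphorylation, with 19 of 37 genes rising and 1 falling, or 20 and 2 adjusted over the list alone (median 0.51, adjusted p = 1.06e-06; adjusted p = 0.223 with an estimated correlation). CYC1 (2.37 ± 0.28) and CYCS, cytochrome c (2.07 ± 0.15), were among them. Glycolysis genes rose in 12 of 22 cases and fell in 2, or 13 and 2 adjusted over the list alone (median 1.05, adjusted p = 1.78e-05; adjusted p = 0.1 with an estimated correlation). PKM was at 2.64 ± 0.33 and PDK1, which restrains pyruvate oxidation, at −2.27 ± 0.19. Heat shock genes rose in 10 of 16 cases and fell in 2, or 11 and 3 adjusted over the list alone (median 1.54, adjusted p = 2.09e-05; adjusted p = 0.0868 with an estimated correlation), with HSPE1 at 2.34 ± 0.22. Immediate early genes rose in 11 of 22 cases and fell in 5, or 12 and 5 adjusted over the list alone (median 0.77, adjusted p = 0.00612; adjusted p = 0.1 with an estimated correlation). EGR1 was at 3.76 ± 0.36 and the chemokine receptor gene CXCR4 at −3.50 ± 0.14. The list's call ended after quantile normalization (adjusted p = 0.0505). Type I interferon response genes fell in 19 of 40 cases and rose in 0, or 20 and 0 adjusted over the list alone (median −1.34, adjusted p = 1.82e-04; adjusted p = 0.604 with an estimated correlation), with TRIM22 at −2.77 ± 0.38. Cytosolic ribosomal protein genes had 8 falls of 30, and 1, RPL38 (−0.84 ± 0.21), adjusted over the list alone (median −0.35, adjusted p = 0.00959; adjusted p = 0.566 with an estimated correlation). With the mean of its probe sets RPL38 was at −0.03 (adjusted p = 0.938). With 75th percentile scaling that list's median was −0.04 and the call ended (adjusted p = 0.374).

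Monocyte markers fell in 7 of 11 cases, 9 adjusted over the list alone, and rose in 0 (median −2.30, adjusted p = 0.00274; adjusted p = 0.625 with an estimated correlation). MNDA was at −4.00 ± 0.42 and S100A9 at −3.36 ± 0.75. Neutrophil markers fell in 5 of 10 cases, 7 adjusted over the list alone (median −1.90, adjusted p = 0.0762). Platelet markers fell in 4 of 10, also 4 adjusted over the list alone (median −0.89, adjusted p = 0.212), and B cell markers in 2 of 8, also 2 adjusted over the list alone (median −0.64, adjusted p = 0.262). With the donor as a block the neutrophil (adjusted p = 0.0327) and platelet (adjusted p = 0.0438) lists passed as well, as did the neutrophil list with 75th percentile scaling (adjusted p = 0.0129) and no filter (adjusted p = 0.0414). The neutrophil list passed too without control replicate 1 (0.0101), control replicate 2 (0.0309) or CD3/CD28 replicate 2 (0.045). T cell markers had 1 rise and 5 falls of 11, or 1 and 6 adjusted over the list alone (median −0.59, adjusted p = 0.34), and passed with quantile normalization (adjusted p = 0.0429).

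**Figure D5:**
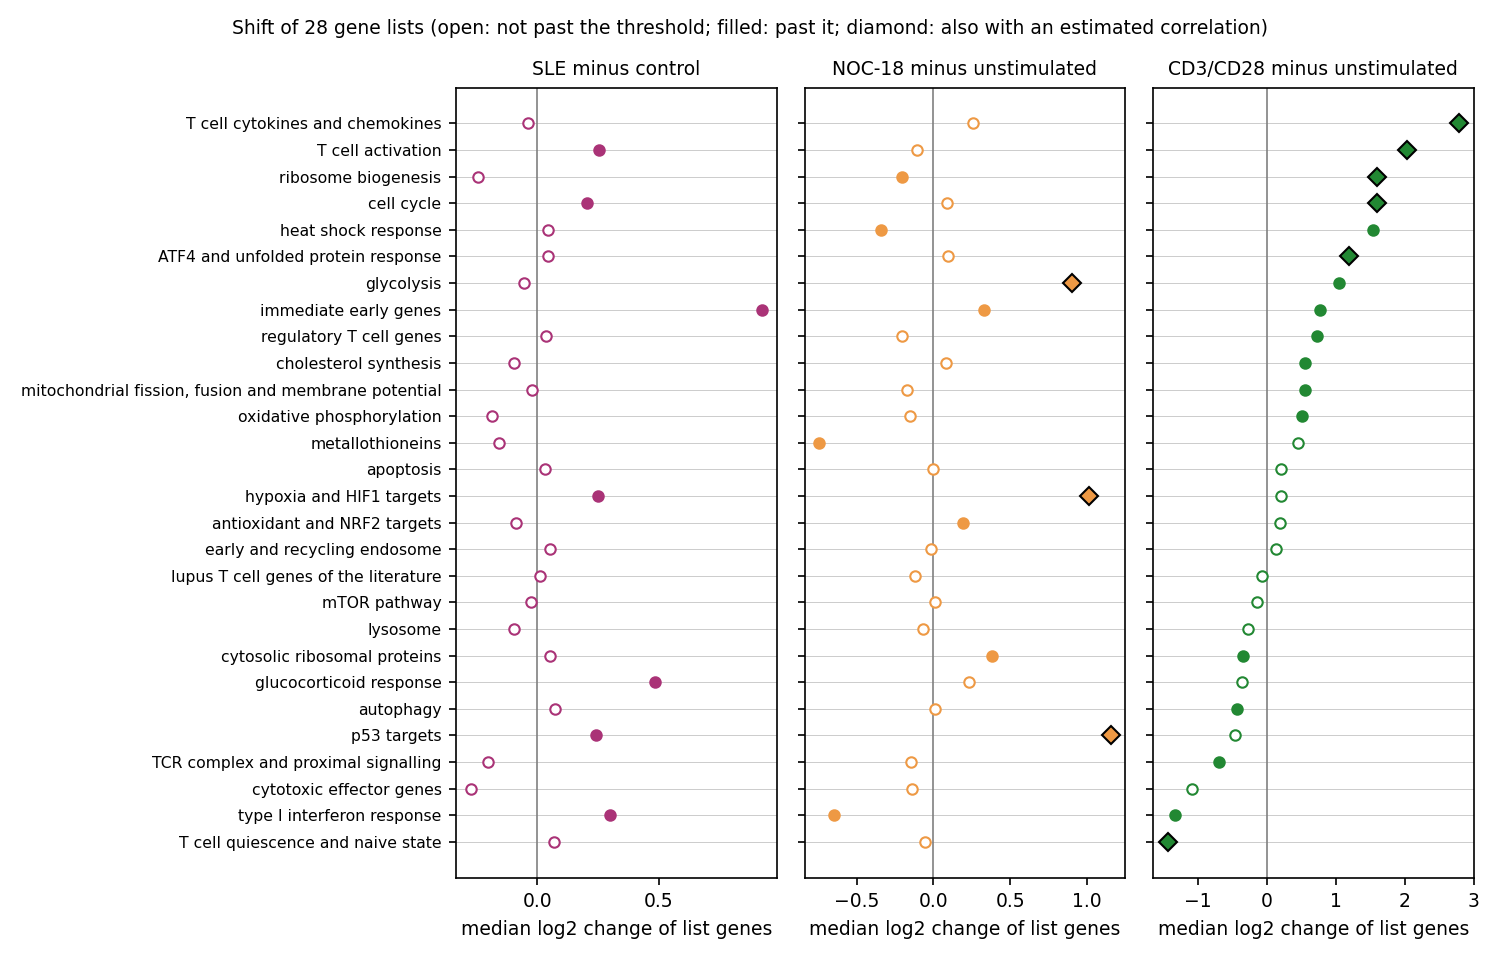
Median log2 change of the measured members of each of 28 process lists in SLE against control, NOC-18 against unstimulated and CD3/CD28 against unstimulated; open symbols mark lists not past the threshold in camera, filled symbols lists past it with the preset correlation, and diamonds lists past it also with an estimated correlation. There were 0 diamonds for SLE, 3 for NOC-18 and 6 for CD3/CD28.

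Setting NOC-18 directly against CD3/CD28 tested the difference of the 2 responses, since the unstimulated level cancels. NOC-18 arrays had the higher level of resting T cell and p53-responsive genes, and CD3/CD28 arrays that of cytokine, activation, growth and division genes. Limma called 5846 genes, 3214 higher with NOC-18 and 2632 lower (55.0% higher; 3996 by at least 2-fold). The median of all genes was 0.30 and moved by −0.27 with quantile normalization and −0.32 with 75th percentile scaling, with which 5340 genes were called and 34.9% of them were higher. PIK3IP1 (5.10 ± 0.14), BNIP3L (4.95 ± 0.21), TP53INP1, a p53-induced gene of autophagy (4.43 ± 0.22), and KLF2 (4.30 ± 0.27) were higher with NOC-18. IL2 (−7.78 ± 0.43), IFNG (−6.33 ± 0.55) and PSAT1 (−5.31 ± 0.19) were lower. CD247 was higher by 2.02 ± 0.30 (adjusted p = 3.85e-05), with LCK at 1.10 ± 0.18, FCER1G at 2.24 ± 0.28, SYK at 1.77 ± 0.52 (adjusted p = 0.0106; 0.121 after quantile normalization) and TFRC at −1.94 ± 0.21, although another TFRC probe set was at 2.03 (unadjusted p = 0.00105) and the mean of its probe sets at −0.26 (adjusted p = 0.48). The other CD247 probe set was at 0.60 (unadjusted limma p = 0.352). The remaining TFRC probe sets were at −2.25 (unadjusted limma p = 1.53e-10), −0.13 and 1.01.

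In this contrast 7 lists held with both correlations. Lower with NOC-18 were T cell activation (27 of 33 lower, 0 higher, the same adjusted over the list alone; median −2.14, adjusted p = 1.09e-17, and adjusted p = 0.00731 with an estimated correlation), and cytokines and chemokines (17 of 25 lower, 3 higher, the same adjusted over the list alone; median −3.00, adjusted p = 5.79e-08). So were cell cycle (27 of 39 lower, 1 higher, 28 and 1 adjusted over the list alone; median −1.64, adjusted p = 1.76e-11), ribosome biogenesis (21 of 26 lower, 1 higher, 22 and 1 adjusted over the list alone; median −2.04, adjusted p = 4.51e-14) and ATF4 targets (13 of 26 lower, 3 higher, 14 and 3 adjusted over the list alone; median −0.94, adjusted p = 1.24e-06). Higher were quiescence genes (18 of 23 higher, 1 lower, the same adjusted over the list alone; median 1.5, adjusted p = 1.43e-08) and p53 targets (15 of 23 higher, 2 lower, the same adjusted over the list alone; median 1.42, adjusted p = 3.13e-05, and adjusted p = 0.0426 with an estimated correlation). Hypoxia-induced genes were higher in 12 of 20 cases and lower in 2, or 12 and 3 adjusted over the list alone (median 1.30, adjusted p = 1.85e-04; adjusted p = 0.108 with an estimated correlation). Glycolysis genes, with 5 higher and 5 lower of 22, the same adjusted over the list alone, were not called (adjusted p = 0.574), so no difference between the 2 responses was shown for that list.

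The last comparison set the SLE profile beside the stimulated profiles, with controls 5 to 9 as the baseline for SLE and controls 1 to 4 for the stimulated cells, so that no array was shared. Across 13124 genes, which are not independent replicates, the log2 differences in SLE correlated with those after NOC-18 at a Pearson r of −0.0591 (Spearman −0.0718), within the −0.353 to 0.348 that random splits of the SLE and control arrays gave. With CD3/CD28 the r was −0.00635 (Spearman −0.00468; splits −0.0734 to 0.0673). Of 401 genes changed by NOC-18, 224 (55.9%) differed in the same direction in SLE, and of 4961 changed by CD3/CD28, 2495 (50.3%). Shares at least as far from an even share, in either direction, came from 82 and 95 of 100 splits. The NOC-18 r turned to 0.0446 without control replicate 8 (63.1% in the same direction), 0.126 without control replicate 9 (70.6%), 0.0256 without control replicate 3 and 0.135 without the 6 poorly correlating arrays (78.1%). The CD3/CD28 r ran from −0.0378 to 0.0380 when any 1 array was left out. Other splits of the arrays, a test added after these values were seen, gave an r at least as far from 0 in 860 of 1001 cases without control replicate 8, 556 of 1001 without control replicate 9 and 22 of 84 without the 6 arrays. For NOC-18, shares at least as far from an even share, in either direction, came from 563, 290 and 14 of these. By r, no likeness of the SLE profile to either response was detectable beyond that of such splits. Without the 6 arrays the NOC-18 share, 78.11%, lay just above the 15.78% to 78.05% that held 95% of the splits. The other shares set against splits lay inside such ranges. That share rests on 6 SLE and 3 control arrays, left after a choice made once results were seen, so no conclusion is drawn from it. With all 9 controls shared, the NOC-18 r was 0.206 and the covariance 0.0439. Simulated unchanged groups gave 0.400 and 0.0685 from the shared controls alone. That simulation gave controls 1 to 4 the spread of all unstimulated arrays, the 6 poorly correlating ones included. None of those 6 is among controls 1 to 4, so the simulated values may be too high and no conclusion is drawn from them.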

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

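No test here was chosen only after the result was seen. Where the highest or lowest array of a group stood far from the nearest other, the share of the group's range taken by that gap is given (Dixon's ratio). Of 522 groups looked at, 43 passed its 95% limit, 25 of 358 genes, 16 of 148 list means and 2 of 16 array measures. Chance flags about 1 in 20 groups.

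Control replicate 3 had a 3 prime to 5 prime ratio of GAPDH of 35.9, with the nearest control at 7.11 (ratio 0.917), and control replicate 9 a mean log2 spike-in signal of 14.33, with the nearest at 13.31 (0.529).

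For single genes, the values on the log2 scale were these, among the 4 donors where a control was compared with the stimulated cells. Control replicate 3 had CPT2 at 8.55 (lowest; nearest 8.78, ratio 0.834). Its CYCS was 13.45 (highest; nearest 13.13, ratio 0.91). Its GAPDH was 12.72 (lowest; nearest 14.59, ratio 0.967). Its HSPE1 was 12.12 (highest; nearest 11.44, ratio 0.862). Its LRBA was 11.41 (highest; nearest 10.79, ratio 0.869). Its PDK1 was 11.98 (highest; nearest 11.65, ratio 0.886). Its TNFRSF10B was 11.40 (highest; nearest 10.86, ratio 0.882). CD3/CD28 replicate 2 had CSGALNACT1 at 7.39 (highest; nearest 6.73, ratio 0.913). Its GINS2 was 12.27 (highest; nearest 11.72, ratio 0.839). Its ZAP70 was 11.04 (highest; nearest 10.87, ratio 0.898). CD3/CD28 replicate 1 had LCK at 12.86 (highest; nearest 12.70, ratio 0.833). Its LGALS12 was 4.61 (lowest; nearest 5.60, ratio 0.952). CD3/CD28 replicate 4 had GABARAPL1 at 7.95 (lowest; nearest 8.70, ratio 0.929). Its TNF was 14.40 (highest; nearest 13.79, ratio 0.894). NOC-18 replicate 4 had GAPDH at 16.38 (highest; nearest 15.82, ratio 0.849). Its TSPAN13 was 8.41 (lowest; nearest 9.27, ratio 0.89). Control replicate 1 had IRF4 at 10.36 (highest; nearest 9.44, ratio 0.864). Its MIR210HG was 5.02 (lowest; nearest 6.92, ratio 0.84). Control replicate 4 had EPOP at 5.87 (lowest; nearest 8.14, ratio 0.904). Its EPSTI1 was 11.37 (lowest; nearest 12.68, ratio 0.936). NOC-18 replicate 1 had TNFAIP3 at 15.36 (highest; nearest 14.74, ratio 0.897). NOC-18 replicate 2 had P2RY10 at 13.59 (highest; nearest 13.21, ratio 0.875). NOC-18 replicate 3 had IL2 at 5.30 (lowest; nearest 7.03, ratio 0.874). SLE replicate 2 had RRM2 at 11.88 (highest; nearest 9.39, ratio 0.68). Control replicate 9 had MTOR at 6.17 (lowest; nearest 8.61, ratio 0.776).

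For the means of gene lists per array, the values on the log2 scale were these. CD3/CD28 replicate 3 had the mean of autophagy at 9.81 (lowest; nearest 9.91, ratio 0.898). Its mean of immediate early genes was 11.49 (lowest; nearest 11.71, ratio 0.869). CD3/CD28 replicate 4 had the mean of apoptosis at 10.57 (lowest; nearest 10.84, ratio 0.905). Its mean of T cell cytokines and chemokines was 11.78 (highest; nearest 11.51, ratio 0.909). SLE replicate 1 had the mean of erythrocyte markers at 10.63 (highest; nearest 7.71, ratio 0.735). Its mean of glycolysis was 12.84 (highest; nearest 12.22, ratio 0.555). SLE replicate 2 had the mean of cell cycle at 9.42 (highest; nearest 8.60, ratio 0.666). Its mean of cytotoxic effector genes was 12.37 (highest; nearest 10.73, ratio 0.486). Control replicate 9 had the mean of autophagy at 9.76 (lowest; nearest 10.25, ratio 0.73). Its mean of mitochondrial fission, fusion and membrane potential was 10.07 (lowest; nearest 10.48, ratio 0.522). CD3/CD28 replicate 2 had the mean of lupus T cell genes of the literature at 11.26 (highest; nearest 11.21, ratio 0.862). NOC-18 replicate 2 had the mean of TCR complex and proximal signalling at 12.11 (highest; nearest 11.79, ratio 0.917). NOC-18 replicate 4 had the mean of p53 targets at 11.11 (highest; nearest 10.75, ratio 0.842). SLE replicate 8 had the mean of glucocorticoid response at 10.63 (lowest; nearest 11.47, ratio 0.473). Control replicate 5 had the mean of cytosolic ribosomal proteins at 15.49 (lowest; nearest 15.64, ratio 0.512). Control replicate 8 had the mean of hypoxia and HIF1 targets at 11.04 (highest; nearest 10.59, ratio 0.608).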

How the results depend on the processing

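The tests without the 6 poorly correlating arrays, with those arrays alone, with the class of array as a block, with marker means or the spike-in signal as covariates, and with 75th percentile scaling of lists were chosen only after the result was seen. In SLE, limma called 0 genes under every setting but 2, array weights (831, 287 higher and 544 lower) and the 6 poorly correlating arrays alone (141, 138 higher and 3 lower). Process lists past the threshold in SLE, 7 at first, were 11 with marker covariates and 0 with an estimated correlation, and cell type lists, 2 at first, were 0 with either. The interferon list in SLE reversed to −0.62 without the 6 arrays, and metallothioneins to 0.58 with marker covariates. Genes changed by NOC-18 were 267 with 75th percentile scaling, 237 without the trend, 203 with the mean of probe sets, 169 with only the 2 groups compared, 119 with all 9 controls and 128 with the spike-in covariate, and study genes 0 with the mean of probe sets. Testing all probe sets, and so more features, gave 9814 for CD3/CD28 and 11550 for NOC-18 against CD3/CD28, which was 2717 with the spike-in covariate. Process lists with an estimated correlation were 3, 6 and 7 for NOC-18, CD3/CD28 and their difference. Cell type lists for CD3/CD28, 1 at first, were 2 with no filter, 2 with quantile normalization, 2 with 75th percentile scaling, 3 with the donor block and 0 with an estimated correlation. For NOC-18 against CD3/CD28 they were 0 with pseudocount 64, 0 with no filter, 2 with quantile normalization, 2 with 75th percentile scaling, 2 with the donor block and 0 with an estimated correlation, and study genes 3 with the mean of probe sets. The correlation of the SLE profile with NOC-18 was 0.206 with shared controls and 0.135 without the 6 arrays, and with CD3/CD28 0.0201 and −0.0381. The cause was not tested, except that fewer arrays or genes enter by construction with only 2 groups or the 6 arrays alone.

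Leaving out each array in turn gave 0 genes in SLE, 215 to 473 for NOC-18, 4481 to 4932 for CD3/CD28 and 5128 to 6363 for their difference. Process lists ran from 5 to 9, 9 to 13, 17 to 18 and 15 to 17, cell type lists from 1 to 3, 0 to 0, 1 to 2 and 0 to 2, and study genes stayed at 0, 1, 5 to 7 and 5. The profile correlations ran from −0.168 to 0.126 for NOC-18 and from −0.0378 to 0.0380 for CD3/CD28.

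With the donor as a replicate block, the counts were 519, 5384 and 6148 genes, 10, 17 and 17 process lists and 1, 6 and 5 study genes. SLE numbers pair no samples, and that block gave 0 genes; same-numbered deviations correlated from −0.372 to 0.292. The block brought past the threshold IFITM1 and EPSTI1 after NOC-18, the neutrophil and platelet lists after CD3/CD28, and, between NOC-18 and CD3/CD28, the interferon (adjusted p = 0.0287) and platelet (adjusted p = 0.037) lists. It changed no other call of a named gene or list. On arrays, signal over background limits what can be seen, so a change of a dim gene is understated.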

Other observations

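The tests on the 6 poorly correlating arrays and on the 8 arrays with a high immediate early mean, the fit with the spike-in signal as a covariate, the tests of an explanation as the whole cause and the test of list means were chosen only after the result was seen, and the glucocorticoid pattern was picked after its shift was seen.

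Stimulation through CD3 and CD28 also changed groups of genes outside the antigen response itself. Cholesterol synthesis genes rose in 7 of 16 cases and fell in 1, the same adjusted over the list alone (median 0.56, adjusted p = 0.00959; adjusted p = 0.0862 with an estimated correlation), with HMGCS1 at 1.25 ± 0.26 (SE). Regulatory T cell genes rose in 6 of 13 cases and fell in 2, or 7 and 2 adjusted over the list alone (median 0.73, adjusted p = 0.0306; adjusted p = 0.123 with an estimated correlation), although CTLA4 and IL2RA, 2 of the risers, are also in the activation list. Genes of mitochondrial fission, fusion and membrane potential rose in 10 of 23 cases and fell in 3, or 12 and 3 adjusted over the list alone (median 0.55, adjusted p = 0.00254; adjusted p = 0.137 with an estimated correlation), with VDAC1, the outer membrane channel, at 2.42 ± 0.19 and PINK1, a sensor of damaged mitochondria, at −2.24 ± 0.24. Autophagy genes fell in 11 of 26 cases and rose in 1, the same adjusted over the list alone (median −0.43, adjusted p = 0.0342; adjusted p = 0.0916 with an estimated correlation, and 0.104 with 75th percentile scaling), with GABARAPL1 at −1.95 ± 0.23. Cytotoxic effector genes moved apart, with 6 of 21 rising and 10 falling, or 6 and 12 adjusted over the list alone (adjusted p = 0.102), GZMB, granzyme B of activated cells, at 3.30 ± 0.39 and GZMK at −3.53 ± 0.30, and that list passed after quantile normalization (adjusted p = 0.0374) and without control replicate 4 (0.025). Genes described in lupus T cells had 11 rises and 10 falls of 27, or 12 and 11 adjusted over the list alone (adjusted p = 0.334), p53 targets 5 and 7 of 23, or 5 and 8 (adjusted p = 0.579), hypoxia-induced genes 7 and 7 of 20, or 8 and 7 (adjusted p = 0.719), and glucocorticoid-responsive genes 8 and 9 of 20, the same adjusted over the list alone (adjusted p = 0.27). Antioxidant genes and NRF2 targets had 10 rises and 8 falls of 26, the same adjusted over the list alone (adjusted p = 0.094, and 0.0484 with no filter), and apoptosis genes 6 and 5 of 19, or 6 and 6 (adjusted p = 0.54).

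Between NOC-18 and CD3/CD28, further lists differed with the preset correlation only. Cytosolic ribosomal protein genes were higher with NOC-18 in 25 of 30 cases, 26 adjusted over the list alone, and lower in 0 (median 0.74, adjusted p = 8.52e-07; adjusted p = 0.234 with an estimated correlation). Oxidative phosphorylation genes were lower in 21 of 37 cases and higher in 3, the same adjusted over the list alone (median −0.65, adjusted p = 4.28e-07; adjusted p = 0.216 with an estimated correlation), with CYCS at −2.36. Heat shock genes were lower in 10 of 16 cases, also 10 adjusted over the list alone, with HSPE1 at −3.17 (median −1.77, adjusted p = 1.76e-06; adjusted p = 0.0533 with an estimated correlation), and metallothioneins in 5 of 8, 6 adjusted over the list alone (median −1.36, adjusted p = 0.00402; adjusted p = 0.31 with an estimated correlation), with MT1E at −1.90. T cell receptor complex genes were higher with NOC-18 in 11 of 25 cases and lower in 2, or 12 and 2 adjusted over the list alone (median 0.51, adjusted p = 0.0234; adjusted p = 0.242 with an estimated correlation, 0.0646 with 75th percentile scaling, and 0.0791 without NOC-18 replicate 2). Monocyte markers were higher with NOC-18 in 6 of 11 cases, 9 adjusted over the list alone (median 1.44, adjusted p = 0.0454; adjusted p = 0.431 with an estimated correlation). That last call ended with pseudocount 64 (adjusted p = 0.052), with no filter (0.0694), and without CD3/CD28 replicate 1 (0.0639), CD3/CD28 replicate 2 (0.0892) or NOC-18 replicate 4 (0.104). Mitochondrial genes were lower with NOC-18 in 14 of 23 cases and higher in 3, or 15 and 3 adjusted over the list alone (median −0.90, adjusted p = 2.97e-04; adjusted p = 0.101 with an estimated correlation). Regulatory T cell genes were lower in 5 of 13 cases and higher in 2, the same adjusted over the list alone (median −0.50, adjusted p = 0.0222; adjusted p = 0.104 with an estimated correlation). Autophagy genes were higher in 10 of 26 cases and lower in 1, the same adjusted over the list alone (median 0.51, adjusted p = 0.0417; adjusted p = 0.101 with an estimated correlation), a call lost with 75th percentile scaling (0.114), without NOC-18 replicate 2 (0.0855) and without CD3/CD28 replicate 2 (0.0518).

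Other splits of the arrays into groups of the same sizes tested whether chance can be excluded. For SLE against control the genes limma called say nothing on this, since with 0 called all 100 of 100 splits give as many by construction. It could not be excluded for the 1231 genes at an unadjusted p under 0.05, since 14 of 100 splits gave as many and the highest other gave 2682. With array weights, the 831 genes called were matched by 3 of 100 splits, the real one included, which is below the share set beforehand. This does not exclude chance, since array weights was the only setting over all 19 arrays that called any gene. The highest other split called 2810, several times as many, which points to a structure of the samples that the groups do not follow. For NOC-18 (403 genes, highest other 7), CD3/CD28 (5109, highest other 0) and their difference (5846, highest other 0), only 1 of the 35 splits, the real one, gave as many. Among the 8 splits that part all 4 donor pairs, the highest other called 0 genes in each of the 3. Only these 8 keep to the pairing, and 1 in 8 is too large a share to exclude chance. In every split but the real one both groups hold arrays of both conditions, so the change itself widens the spread and holds the calls down.

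Genes of long genomic span fell more often after NOC-18 than short ones: the Spearman correlation of the log2 change with gene span was −0.135 (95% bootstrap interval −0.150 to −0.120) over 14026 genes, which are not independent replicates, and the 2805 genes with the longest span (median 152 kb) held 102 falls and 12 rises against 37 and 33 in the 2806 with the shortest. For weaker hybridization, the planned test came out on the side of that cause, with a correlation above −0.1 in donor 2, whose spike-in signal rose least (−0.0825, rise 0.265), but 1 donor decides little, as donors 1, 3 and 4 were at −0.0603, −0.131 and −0.0595 and the rise was largest in donor 4 (0.879). With the spike-in signal as a covariate, which took the genes called from 403 to 128, the correlation was −0.147 (−0.164 to −0.134 over genes). This lies past the bound of −0.1 that was set after the result was seen. The interval leaves out the spread between donors, and the covariate moves with the treatment. Weaker hybridization is thus not excluded, in part or as the whole cause of the trend. Dim probe sets stay open as part of it, since from the dimmest to the brightest of 5 bins by mean signal the correlation was −0.0175, −0.116, −0.229, −0.222 and −0.0946, above −0.1 in 2 bins where the tests needed 3 or 0, and 24 hr of culture shared with CD3/CD28 may as well, since the correlation after CD3/CD28 (−0.111) was higher by only 0.0242 (0.00592 to 0.0456). Hybridization, dim probe sets, culture and an effect of nitric oxide on long transcripts cannot be told apart, because no cultured, unstimulated arrays are at hand and the spike-in level moves with the treatment.

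Glucocorticoid-responsive genes were higher on SLE arrays, by 0.697 (95% interval 0.269 to 1.13) for the mean of the list, a difference that did not pass in the permutation test (adjusted p = 0.0821) nor in camera with an estimated correlation (adjusted p = 0.108). Other blood cells in the preparation may carry part of it: with the monocyte, granulocyte and platelet marker means as covariates the difference was 0.47 (0.162 to 0.771). An immediate early response may too, since the 3 shared genes left out and with that list's mean as a covariate it was 0.405 (0.156 to 0.655), from 0.653. Without the 6 poorly correlating arrays it was 0.659 (0.158 to 1.16), but without the 8 arrays with a high immediate early mean, which include these 6, it was 0.440 (−0.0669 to 0.946), and with these 8 as a class 0.445 (0.116 to 0.775). The intervals with the markers, with the immediate early mean and without the 6 arrays lie above 0, past the bound written afterwards for a whole cause. They take no account of the choice of this list, whose difference did not pass, and the marker means may miss part of the other cells. None of these is therefore excluded as the whole cause, and the 8 arrays stay open as the whole of it too. Since each interval spans 50% of the first value, none of the 4 can be told apart as a part from a difference of the patients themselves, including their treatment, which was not tested.

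Immediate early genes were higher on SLE arrays by 1.15 for the mean of the list (95% interval −0.153 to 2.46) and by a median over genes of 0.929. With the marker means as covariates the median was 0.329 and the mean 0.405 (−0.399 to 1.21), which is consistent with a part for other blood cells. Without the 6 poorly correlating arrays the median was 0.898 and the mean 1.08 (−0.106 to 2.26), but without all 8 arrays with a high mean, which were picked by this mean itself and include SLE replicates 4 and 7, the mean was 0.345 (−0.581 to 1.27). The intervals reach 0 and are too wide for either explanation to be told apart from a difference between patients and controls, or from handling of the blood before RNA was taken, neither of which was tested.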
